A study of Drosophila melanogaster with 2 samples.

How the data were processed

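Hi-C, which ligates and sequences pairs of DNA fragments that lie close to each other in fixed nuclei, was carried out on wild-type Drosophila melanogaster embryos collected 16 to 18 h after egg laying. Per the labels' protocols, 3000 to 4000 embryos were fixed in 2% formaldehyde for 10 min, the chromatin was cut with the restriction enzyme DpnII and ligated, and the DNA was sonicated to 500 to 1500 bp before paired-end sequencing. The labels name 2 libraries of 1 group, replicates 1 and 2. Bowtie and the dm3 assembly are named in the submitters' processing notes, with no version of the aligner, and the filters on read pairs are not given in the sources used here.

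The deposited files hold 9 contact tables, with bins of 2.5, 5, 10, 16, 20, 32, 40, 80 and 160 kb, and a list of domains. Each contact table gives, per the file headers, an observed count and an expected count for every listed pair of bins. No column names a library, so the tables were read as pooled over both libraries; 0 columns could be tied to a single library. Values therefore carry no replicate error, and replicates could not be compared or left out. The deposited observed count per pair of bins is a whole number of contacts that was not normalized. The authors' expected count is not a function of distance: at 16 kb its mean was 2.01 for bins 96 kb apart and 1.96 for bins 10 Mb apart, where the mean observed count was 237 and 5.68. Summed over pairs of bins on different arms it came to nearly the observed total (observed over expected 0.996). It was read as a model of technical bias without distance. The 4 finest tables that stop short of whole arms reach 0.1 Mb (2.5 kb bins), 0.4 Mb (5 kb), 0.8 Mb (10 kb) and 2 Mb (20 kb); the 16 and 32 kb tables hold all pairs of the same arm, and the 40, 80 and 160 kb tables also pairs of different arms. The deposited list of bins has a count per bin that summed to 603373 over the 10 kb bins. It was read as a count of genomic elements, not of reads. The deposited domain list gives start, end and a class number from 1 to 4, with no description in the file, for 1305 domains on 6 chromosome arms. It was presumably called on the same libraries, so that a contrast at its borders describes the list and is not independent evidence.

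For pairs of the same arm, the authors' expected count was multiplied at each distance by the observed sum over the expected sum of that arm (distances over 2 Mb were pooled in steps of about 2%), which gives the expected contacts used below. For pairs of different arms it was scaled to the observed total of that pair of arms, except where arm pairs themselves were compared. Contact decay was the slope of log10 contacts per listed bin pair on log10 distance from 20 kb to 2 Mb at 16 kb, the finest table that holds those distances. Enrichment within domains compared bin pairs up to 400 kb apart inside a domain with pairs at the same distance in neighbouring domains (10 kb table). Insulation was the log2 ratio of observed over expected contacts between the 50 kb on each side of a border or of a domain's centre. Both were set against 1000 circular shifts of the whole domain list along each arm, with two-sided permutation p-values whose smallest value is 0.001. Contacts between arms used the 160 kb table with exact permutation tests over arm pairs and an exact sign test over the 10 pairs of large arms (2L, 2R, 3L, 3R and X) for blocks of 10% of an arm. These tests treat arm pairs as independent, although pairs share arms. Tests with arms as units were added after the data were seen: all 15 ways to name 1 of the 5 arms X and join the others in 2 chromosomes, and all 100000 choices of 1 block in each arm. The compartment pattern was the first eigenvector of the correlation matrix of distance-normalised contacts at 80 kb, with its sign set so that it fell with domain length. Contacts between domain classes used bins of 40 kb on the 5 large arms, at least 2 Mb apart or on different arms, with 1000 circular shifts of the classes. Other comparisons of domains used permutation tests with 100000 resamples, whose smallest p is 1e-05, or Fisher's exact test. Tests over domains or borders treat them as independent, although neighbours are not, and their p-values are then too small. Adjusted p-values are Benjamini-Hochberg, with a threshold of 0.05.

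Comparisons of domain classes, of X with autosomal arms, of chromosome 4 and of loci shifted together were added after the data were seen. The Polycomb list of 19 loci was fixed before the data were examined. Its positions are approximate dm3 positions from general knowledge; they were not checked against an annotation of that build, which was not used here, and no position was converted. The gene table used here names the Release 6 assembly and served for symbols only: all 57 genes of the Polycomb list were found in it, as were all 16 ribosomal protein, 14 muscle, 11 neuron and 7 heterochromatin genes and 12 of 13 cuticle genes of the other lists. Those other lists could not be placed on dm3 and were not analysed here. A domain was taken to hold a locus if it shared at least 10 kb with its window or held the window's midpoint, a rule set after the overlaps were seen. For each pair of loci over 1 Mb apart on an arm (16 kb table), or on different arms (40 kb table), the log2 of observed contacts plus 0.5 over expected contacts was ranked among all pairs of windows of the same sizes (and, on one arm, the same distance) with at least 0.5 times its expected contacts. The median over pairs was compared with 10000 random draws of such windows, which treat pairs as independent, and with 1000 circular shifts that move all loci of an arm together.

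Regions were named by a rule fixed before the data were examined: all loci of the list, the 5 longest domains, the 5 domains with the highest and the 5 with the lowest within-domain ratio among those of at least 50 kb, the 10 pairs of such domains over 1 Mb apart on an arm with the highest ratio among pairs with at least 50 expected contacts, the 5 highest between arms, and the 5 borders with the lowest crossing ratio. Intervals are exact 95% Poisson intervals of the observed count. Contacts are sequenced pairs without molecular identifiers, so intervals cover counting error only. Where a spread is given as SD over arms, the arms are parts of the same pooled libraries and not replicates.

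The steps for domains, borders, domain classes, locus pairs and domain pairs were tested on simulated tables drawn from the expected contacts; contact decay, contacts between arms and of arm ends, the eigenvector, the classes of locus domains and the order of classes along the arms were not. A within-domain effect of 0.58 on the log2 scale over 1305 domains was recovered as 0.57, a class 3 effect of 0.38 as 0.36 on the same arm and 0.37 between arms, and a locus effect of 1 as 0.98 with 38 of 38 same-arm pairs past the threshold and 0 of 38 without an effect. The same effect on different arms was recovered as 0.99, with 126 of 127 pairs past the threshold. Apart from the effect put in, these tables held counting noise only, and all pairs were raised at once. The counts therefore do not give the power for single pairs in the real tables. Of 50013 domain pairs, 20 of 20 raised pairs ranked highest. The class 3 effect moved the class 2 value by -0.0081 with a permutation p of 0.005 (the smallest those shifts give), so class values of that size were not read. Without any locus effect, the median over the 127 pairs on different arms had a permutation p of 0.019 in the simulation. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Alternatives covered bin size, distance range, window, the expected contacts, low-coverage bins (the lowest 5%), domain length, arms and loci left out, and the width of arm ends.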

Results

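The series holds Hi-C contacts of wild-type Drosophila embryos at 16 to 18 h of development, from 2 libraries of 1 group that the deposited tables give as pooled values. There is no second condition, and the comparisons are between parts of the genome: domains, chromosome arms, and loci bound by Polycomb, the repressor complex of developmental genes that is the subject of the series. The tables hold 140496411 contacts, of which 96455001 joined positions of the same arm and 44041410 (31.3%) joined different arms. Neighbouring 16 kb bins shared a median of 1126 contacts. Counting error is therefore small for sums, while biological variation between embryo collections is not measured here. Coordinates are those of the deposited domain list (dm3).

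Contacts on the same arm fell with distance in nearly the same way on all 5 large arms. On 2L, bin pairs of 16 kb held 687 contacts at 32 kb (95% Poisson interval 685 to 688) and 16.0 at 2000 kb (15.8 to 16.3). The slope of log10 contacts on log10 distance had a median of -0.96 over the 5 large arms, with an SD of 0.016 over arms. The single values were -0.96 on 2L, -0.94 on 2R, -0.99 on 3L, -0.97 on 3R and -0.95 on X. Chromosome 4, the small and largely heterochromatic chromosome, had a slope of -0.70 (SE of the fit 0.041). Its distances ended near 1076 kb, so its slope covers a shorter range than those of the large arms. Over the range of 50 kb to 5 Mb the median slope of the large arms was -0.87. The X chromosome lay below the autosomal arms at every distance: between 50 kb and 2 Mb its contacts, over the authors' expected, were 0.666 times those of the 4 autosomal arms at the same distances, which themselves lay between 0.958 and 1.05.

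**Figure D1:**
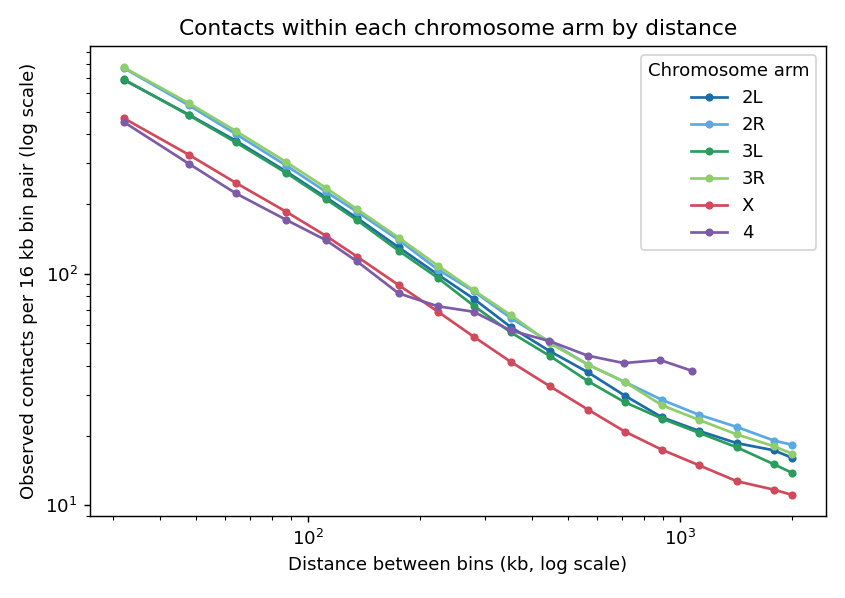
Observed contacts per pair of 16 kb bins (vertical axis, log scale) against the distance between the bins in kb (horizontal axis, log scale), with a line for each chromosome arm. The 5 large arms run nearly parallel, with X below the others, and chromosome 4 flattens at long distances (slope -0.70).

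The domain list divides 117.6 Mb of the 6 arms into 1305 contiguous domains with a median length of 58.6 kb (mean 90.1 kb, SD 85.3, range 10.3 to 730.3 kb). Domains of X had the longest median (72.9 kb) and those of 2R the shortest (53.9 kb). Class 1 held 610 domains with a median of 36.7 kb, or 27.6% of the listed length; class 2 held 505 domains with a median of 97.2 kb and 54.3% of the length. Class 3 held 139 domains (median 84.1 kb, 11.96% of the length) and class 4 held 51 (median 86.8 kb, 6.11%). All 18 domains of chromosome 4 were of class 4, and 26 of the 33 class 4 domains of the large arms lay in the 10% of an arm nearest the centromere. The longest domains were 13,741,950 to 14,472,249 on X (730.3 kb), 15,612,350 to 16,217,049 on 2R (604.7 kb), 1,688,750 to 2,176,349 on 3R (487.6 kb) and 16,887,850 to 17,360,749 on 2L (472.9 kb), all of class 2, and 2,038,650 to 2,500,749 on 2R (462.1 kb), of class 4.

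Contacts inside domains were 1.59 times as dense as contacts at the same distance between neighbouring domains (log2 0.67). The ratio was 0.70 ± 0.027 on the log2 scale over the 5 large arms (SD over arms) and 0.70 on chromosome 4. The 1000 shifts of the list gave a mean of -0.02 and a highest value of 0.07 (permutation p = 0.001, the smallest they can give). The contrast was 1.62-fold at 20 kb, 1.97-fold at 100 kb and 1.30-fold at 400 kb. With a plain mean per distance in place of the authors' expected contacts the log2 ratio was 0.35. The highest densities, relative to the arm's mean at the same distances, were found in the class 4 domain at 23,398,350 to 23,639,449 on 3L (2.15-fold, 95% Poisson interval 2.11 to 2.19) and the class 2 domain at 2,165,650 to 2,233,549 on X (2.05-fold, 2.00 to 2.11). They were followed by 720,150 to 928,249 on 2R (1.93-fold, class 4), 6,908,450 to 6,961,749 on X (1.90-fold, class 2) and 4,892,550 to 5,062,249 on 3R (1.86-fold, class 2). The lowest were 8,731,850 to 8,799,749 on X (0.744-fold, class 2), 13,280,050 to 13,346,249 on 2R (0.765-fold), 12,462,550 to 12,529,049 on 3L (0.784-fold), 15,492,550 to 15,548,749 on 3L (0.812-fold) and 16,679,050 to 16,837,749 on X (0.819-fold), the last 4 of class 1.

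Class 1 domains, the short ones, had the lowest contact density inside. Among domains of at least 50 kb on the large arms, the median was 1.06-fold in 228 class 1 domains, 1.30-fold in 383 class 2 domains, 1.202-fold in 103 class 3 domains and 1.39-fold in 26 class 4 domains. Class 1 lay below class 2 by 0.29, below class 3 by 0.18 and below class 4 by 0.40 on the log2 scale (permutation p = 1e-05 each, the smallest it can give, adjusted p = 2e-05 over 6 comparisons). Class 2 exceeded class 3 by 0.11 (permutation p = 0.00044, adjusted p = 0.000528), and class 3 minus class 4 was -0.21 (permutation p = 9e-05, adjusted p = 0.000135). Class 4 and class 2 differed by 0.10, which did not pass the test (permutation p = 0.0528), although it did with 5 kb bins (unadjusted permutation p = 0.0175) and 20 kb bins (unadjusted permutation p = 0.035). With bin pairs at most 50 kb apart the differences of class 1 from classes 2, 3 and 4 were -0.14, -0.099 and -0.19, that of class 2 from class 3 was 0.045 (unadjusted permutation p = 0.0314) and that of class 3 from class 4 was -0.091 (unadjusted permutation p = 0.0283). These comparisons of classes were chosen after the list was seen to hold them. They were not recomputed with a plain mean or the product of bin totals. Median element counts per 40 kb bin were 267 in class 1, 224 in class 3, 162 in class 2 and 125.5 in class 4. The densities ran in the reverse order, so the authors' bias model was not excluded as a source of these differences.

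Contacts across domain borders were depleted to 0.664 times the expected value (mean log2 -0.59 over 1291 borders), against 0.963 at the centres of domains. Shifted borders gave a mean of 0.02 and a lowest value of -0.08 (permutation p = 0.001, the smallest the shifts can give). Borders of X were the deepest (-0.68) and those of chromosome 4 the shallowest (-0.40). With the authors' expected contacts, the class on each side went with the depth. This class contrast was also computed with a plain mean per distance, but that value was not kept. Its dependence on the expected contacts is therefore not known. On the large arms, 951 borders with a class 1 domain on at least one side had a mean of -0.67 (SD 0.33). The 323 others had a mean of -0.37 (SD 0.35), a difference of -0.30 (permutation p = 1e-05, the smallest it can give). This difference held its direction on each of the 5 large arms (from -0.36 to -0.25). It was -0.16 with a 20 kb window and -0.36 with a 100 kb window. The median class 1 domain was 36.7 kb long, so a 50 kb window often reached past it and over a second border. Domain length was not separated from class here. Borders between class 1 and class 3 averaged -0.70 (142 borders), those between class 2 domains -0.36 (185) and those between class 4 domains 0.00 (18, SD 0.56). The lowest crossing ratio was 0.282 (95% Poisson interval 0.270 to 0.294) at 18,180,850 on 3R, followed by 10,201,450 on 2L (0.299), 15,593,450 on X (0.302), 16,168,150 on X (0.310) and 4,462,850 on 2L (0.325); each had a class 1 domain on one side. With a plain mean per distance the borders at 15,593,450 on X and 4,462,850 on 2L were shallower (log2 -0.83 and -0.70, against -1.73 and -1.62), as was that at 16,168,150 on X with 20 kb bins (-0.97 against -1.69).

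Among the 10 pairs of large arms, the 2 pairs from the same chromosome had the highest contact. Observed over expected contacts were 1.39 for 2L with 2R and 1.24 for 3L with 3R, against a mean of 0.906 (SD 0.124) over the other 8 pairs of large arms (exact permutation p = 0.0222, the smallest value that 45 splits can give). These splits treat arm pairs as independent, although pairs share arms; with the 5 arms renamed as units, a test added later, the exact permutation p was 0.0667, the smallest that 15 namings can give, so the difference is not established. The difference of 0.41 was 0.27 with the product of the arms' totals. Pairs of autosomal arms from different chromosomes lay between 0.975 and 1.06. X with the 4 autosomal arms stood at 0.841 with 2R, 0.794 with 3L, 0.775 with 2L and 0.767 with 3R, or 0.780 times the autosomal value on average (exact permutation p = 0.0286 over 70 splits, the smallest they can give), a comparison chosen after the values were seen. All 4 pairs share X, and with the arms renamed as units the exact permutation p was 0.2, so this is a description of 1 arm. Expected contacts from the product of the arms' totals remove this difference by their construction. Chromosome 4 met the autosomal arms at 1.35 to 1.47 and X at 1.02. Its contacts were denser with the centromere-proximal 10% of each large arm than with the rest of that arm, by 2.64-fold on 3L, 2.53-fold on 2R, 2.06-fold on 2L, 1.98-fold on 3R and 1.26-fold on X. Other expected contacts were not run for chromosome 4.

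The ends of different arms met like with like. Blocks next to the centromeres were in contact 1.86 times as often as blocks of the arms' interiors (mean log2 difference 0.89, SD 0.47 over arm pairs), and blocks next to the telomeres 1.81 times as often (0.85, SD 0.16). Both held in 10 of 10 pairs of large arms (exact sign test p = 0.00195 each), which share 5 arms and are not independent. Over all 100000 choices of 1 block of 10% in each arm, a test added later with arms as units, the exact permutation p was 1e-05 for centromeres, the smallest it can give, and 2e-05 for telomeres; it treats the blocks of an arm as exchangeable. Contact between centromere-proximal blocks was highest for 2L with 2R (3.79-fold over that pair's mean) and lowest for 3R with X (1.29-fold). Centromere-proximal blocks of one arm and telomere-proximal blocks of another did not stand apart from the interior (mean log2 difference 0.06, above 0 in 6 of 10 pairs, exact sign test p = 0.754). With blocks of 5% of the arm the log2 differences were 1.53 for centromeres and 1.16 for telomeres. Expected contacts other than the authors' were not run for arm ends. Most class 4 domains of the large arms lay in the centromere-proximal blocks. Between arms, class 4 with class 4 stood at -0.13 on the log2 scale with a plain mean.

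**Figure D2:**
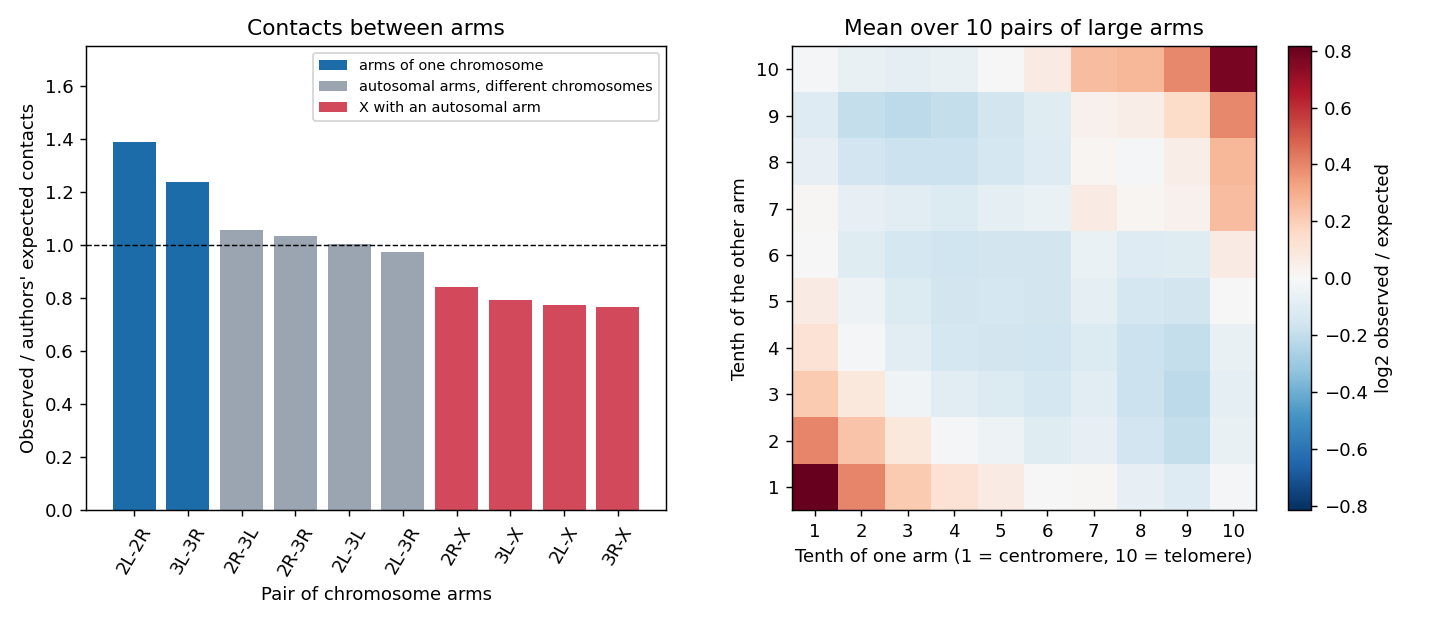
Left, observed over the authors' expected contacts (vertical axis, ratio) for each pair of large arms (horizontal axis), coloured by kind of pair; right, mean log2 observed over expected contacts over 10 pairs of large arms for each block of 10% of the arms, numbered from centromere to telomere. Arms of the same chromosome lie at 1.39 and 1.24 and X pairs at 0.767 to 0.841, and the corners where centromere meets centromere and telomere meets telomere are the densest (mean log2 0.82 and 0.78).

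The first eigenvector of the distance-normalised contact maps divided the bins of each arm by sign. The signs come from the same contacts, so a higher contact of like with like is partly built in; no null was run and the ratio is a description only. Beyond 2 Mb, bins of like sign in the first eigenvector met 1.29 times as often as bins of unlike sign (log2 0.37). By arm the log2 value was 0.53 on X, 0.43 on 2L, 0.37 on 3R and 0.36 on 3L. On 2R the eigenvector gave 98.1% of bins the same sign and a value of -0.42, so it gave no such division there. After the correlation matrix was centred, an alternative chosen after this was seen, 58.0% of 2R bins were positive and its value was 0.31. The sign followed the domain classes: 401 of 407 bins in class 1 domains were positive (98.5%), against 525 of 806 in class 2 (65.1%), 121 of 165 in class 3 (73.3%) and 59 of 70 in class 4 (84.3%). The orientation of the sign was set from domain length, and class 1 domains are short; the counts include 2R, where nearly all bins were positive.

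Class 1 domains met each other over long distances. On the same arm beyond 2 Mb, contacts between class 1 bins were 1.38 times the expected value (log2 0.47, adjusted permutation p = 0.002), above 0 on 5 of 5 arms, and between arms 1.25 times (0.32, adjusted permutation p = 0.002), above 0 in 10 of 10 arm pairs. These log2 values were 0.99 and 0.86 with a plain mean in place of the authors' expected contacts, and between arms 0.069 with the product of the bins' total contacts, each past the threshold. Contacts between class 2 and class 3 bins were below expectation on the same arm (0.903 times) and between arms (0.888 times), each with an adjusted permutation p of 0.002 over 20 comparisons and on 5 of 5 arms and in 10 of 10 arm pairs. Class 2 with class 3 was also computed with the plain mean and the product of bin totals, but those values were not kept. How it depends on the expected contacts is therefore not known. Contacts between class 4 bins of different arms were 2.06 times the expected value (adjusted permutation p = 0.002, 6 of 6 arm pairs), but at -0.13 on the log2 scale, below expectation and without passing the test (adjusted permutation p = 0.423), with the plain mean, and at 0.68 without the outer 10% at both ends of each arm, 0.67 with the product of bin totals and 0.64 without 2R, each past the threshold. On the same arm class 4 stood at 1.43-fold (adjusted permutation p = 0.00922), with 2 of 3 arms above 0 (log2 1.05 on 2L, 0.24 on X and -0.38 on 2R), but at -0.49 on the log2 scale with the plain mean (adjusted permutation p = 0.125), and at 0.042 without the outer 10% at both ends of each arm (adjusted permutation p = 0.607) and 0.22 without 2L (adjusted permutation p = 0.328), and at 1.01 without X. Class 3 with class 3 depended on the expected contacts used: the log2 value was 0.07 on the same arm (adjusted permutation p = 0.0613) and -0.08 between arms (adjusted permutation p = 0.04995, lost when 2L, 3L, 3R or X was left out), but 0.31 and 0.17 with the plain mean and 0.14 and 0.07 with the product of the bins' total contacts, each of these last 4 past the threshold. Class 2 with class 2 between arms stood at -0.16, at -0.37 with the plain mean and at 0.036 with the product of bin totals, each past the threshold. All comparisons of classes were chosen after the list was seen to hold them.

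**Figure D3:**
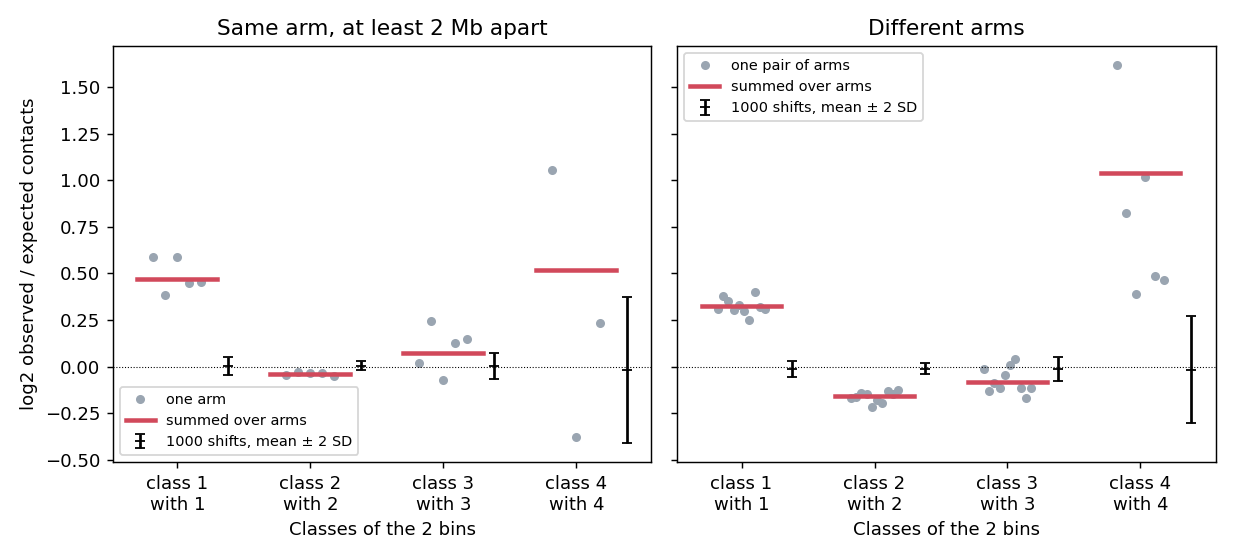
Log2 observed over expected contacts (vertical axis) between bins of the same domain class (horizontal axis) for the same arm beyond 2 Mb (left) and for different arms (right). Grey points are single arms or pairs of arms, red lines the value summed over them, and black bars the mean ± 2 SD of 1000 shifts of the classes; class 1 lies at 0.47 and 0.32, outside the shifts.

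Most of the Polycomb loci lay in class 3 domains. Of 19 loci fixed in advance, the domain with the largest overlap was of class 3 for 14, class 2 for 4 and class 1 for 1, where the share of class 3 in the listed length (11.96%) would give 2.27 (two-sided exact binomial p = 7.87e-10). The positions of the loci are approximate, and the test treats loci as independent although escargot and snail share a domain. How the classes were made is not described, so Polycomb binding may have gone into them. In that case the overlap is not independent evidence. By domains, 18 of the 24 that held a locus were of class 3, against 121 of 1281 others (9.45%; Fisher's exact p = 8.52e-14, adjusted p = 3.41e-13 over 4 classes), while class 1 was rarer among them (2 of 24 against 608 of 1281; Fisher's exact p = 9.06e-05, adjusted p = 0.000181). The Antennapedia complex, the Hox cluster from lab to Antp, covered 3 class 3 domains from 2,486,350 to 2,891,449 on 3R. The bithorax complex, with Ubx and Abd-B at its ends, covered 2 class 3 domains that met at 12,625,650 on 3R. The invected and engrailed pair, segment polarity homeobox genes, lay in a class 3 domain of 166.6 kb on 2R (7,339,350 to 7,505,949), and Psc with Su(z)2, which encode Polycomb group proteins, in a domain of 90.6 kb (8,841,850 to 8,932,449) with a density of 1.53-fold from 15743 contacts, the highest among the class 3 domains with a locus. The even skipped, vestigial, Distal-less, wingless, eyes absent, spalt, dachshund, escargot and snail loci also lay in class 3; escargot and snail shared the domain from 15,273,150 to 15,499,349 on 2L. The exceptions were elbow B with no ocelli, the Dorsocross genes and hedgehog, in class 2 domains of 343.8, 334 and 405.4 kb, polyhomeotic, in a class 1 domain of X, and the odd skipped cluster, which overlapped 2 class 3 domains and most with the class 2 domain from 3,633,050 to 3,657,149 on 2L. Domains with a locus were longer than the others (median 139 kb, SD 103, n = 24, against 57.4 kb, SD 84.6, n = 1281; permutation p = 0.00039), by 81.7 kb, or by 46.4 kb among domains of at least 50 kb (permutation p = 0.042), and also within class 3 (132 against 78.3 kb, n = 18 and 121; permutation p = 0.00987). A longer domain is more likely to hold a given window, which this comparison does not remove. Their contact density did not differ detectably (median log2 0.28, SD 0.20, n = 23, against 0.21, SD 0.29, n = 1234; permutation p = 0.271).

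Among pairs of Polycomb loci on different arms, 0 of 127 passed the threshold. On the same arm 0 of 38 did, but with 227 to 1432 windows to rank against, a pair that stood alone could reach an adjusted p of 0.0531 at the least, so single same-arm pairs were not decided by this test. Between arms, even Dll with ph at 2.42-fold did not pass (exact rank p = 0.00477, adjusted p = 0.303). The count of 0 of 127 thus does not exclude raised single pairs. The Antennapedia and bithorax complexes, 9.65 Mb apart on 3R, shared 1.56 times the 2344 contacts expected (95% Poisson interval 1.51 to 1.61); 4 of 1100 window pairs at that distance were as high, the pair itself included (two-sided exact rank p = 0.00727, adjusted p = 0.186 over 38 pairs). The bithorax complex and the tinman, bagpipe and ladybird cluster of mesodermal homeobox genes shared 2408 contacts, 1.79-fold (1.72 to 1.87; exact rank p = 0.00978, adjusted p = 0.186). On 2R, 8 of 9 pairs lay above expectation, with even skipped and vestigial at 1.72-fold and vestigial and Distal-less at 1.71-fold, each below the threshold. Their median of 1.52-fold had a permutation p of 0.021 when the loci of the arm were shifted together (adjusted p = 0.0629 over 3 arms); draws that treat pairs as independent gave an adjusted permutation p of 0.0009. On 2L, 3 of 23 pairs lay above expectation (median 0.859-fold). Over all 38 same-arm pairs the median was 0.896-fold (permutation p = 0.518 with loci shifted together and 0.39 with independent draws), and over 127 pairs on different arms 0.996-fold (permutation p = 0.526 and 0.0721). Without any effect, a share of about 0.05 of pairs would have an unadjusted exact rank p under 0.05. Against that share, 10 of 127 single pairs on different arms had such a p, 7 of them above expectation, and 2 of 38 on the same arm. Of those 7, 6 involved the polyhomeotic locus; without it the median over pairs on different arms was -0.073 on the log2 scale (permutation p = 0.78 with independent draws).

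The result for the list as a whole rested on the authors' expected contacts. With a plain mean per distance, planned for the same arm and added later between arms, the median log2 values were 0.54 and 0.37 (permutation p = 0.00699 and 0.037 with loci shifted together), and with the product of the bins' total contacts, added later, 0.16 and 0.16 (permutation p = 0.047 and 0.001). Between arms, 0 of 127 single pairs passed the threshold under either. Bins of 16 kb in the loci held a median of 88 of the elements counted by the authors (SD 36.0, 96 bins), against 76 (SD 39.2, 7271 bins) elsewhere.

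**Figure D4:**
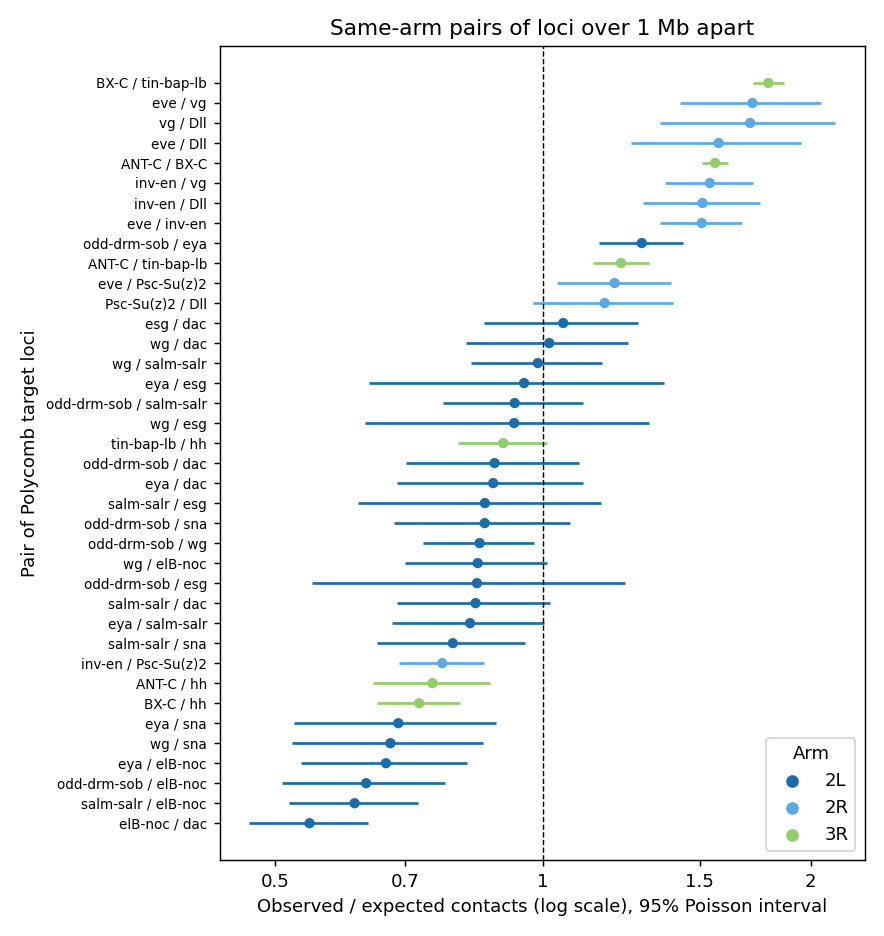
Observed over expected contacts (horizontal axis, log scale) with 95% Poisson intervals for the 38 pairs of Polycomb loci over 1 Mb apart on the same arm (vertical axis), coloured by arm. The pairs of 2R lie mostly to the right of 1 (8 of 9) and those of 2L mostly to the left (3 of 23 above), and the Antennapedia and bithorax complexes stand at 1.56.

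The strongest distal contacts on the arms joined domains of class 2 with class 2 in 7 of the 10 highest pairs, and none of these domains held a locus of the Polycomb list. Class 2 with class 2 made up 26.9% of all pairs compared, and only 24 of all 1305 domains held a locus. Among 50013 pairs of domains over 1 Mb apart the median ratio was 0.967 and the 99th percentile 2.01. The highest was 19.5-fold (95% Poisson interval 19.0 to 19.9) between the class 4 domains 20,099,550 to 20,292,949 and 21,683,750 to 21,755,949 of 2L. It was followed on 2R by 4,610,850 to 4,779,349 with 10,883,150 to 11,001,849 (15.8-fold, 15.5 to 16.1, from 11335 contacts) and on 3L by 12,829,050 to 12,998,749 with 18,676,950 to 18,739,549 (15.3-fold, 14.8 to 15.9). The same 3L domain met 19,921,950 to 19,996,349 at 6.14-fold. On X, 839,350 to 1,129,749 and its neighbour 651,550 to 839,349 met 15,900,450 to 15,999,549 at 11.1-fold and 8.83-fold, and 5,327,550 to 5,420,749 met 17,471,350 to 17,522,849 at 10.7-fold. The rest of the 10 highest were 1,988,050 to 2,129,549 with 10,862,350 to 10,966,049 on 2L (10.6-fold), 4,553,850 to 4,610,849 with 17,608,850 to 17,948,849 on 2R (7.44-fold) and 952,450 to 1,043,549 with 7,843,450 to 8,046,249 on 3R (7.30-fold). With a plain mean per distance these 10 ratios lay between 4.92 and 11.2, and that of the highest pair was 7.03. The genes in these domains are not named, since no annotation of dm3 was used here.

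Between arms, 4 of the 5 highest ratios joined class 4 domains at the centromere-proximal ends of 2L and 2R. The highest was 22,274,650 to 22,494,049 on 2L with 720,150 to 928,249 on 2R (11.96-fold, 95% Poisson interval 11.3 to 12.7), and the same 2L domain met 475,150 to 702,549 at 10.3-fold and 1,170,550 to 1,551,549 at 9.72-fold. The domain 22,169,350 to 22,237,349 of 2L met 1,170,550 to 1,551,549 of 2R at 8.85-fold. The exception joined the last listed domains of 2R (20,973,250 to 21,069,049, class 3) and 3R (27,637,850 to 27,872,649, class 2), at the telomeric ends, at 10.9-fold (10.4 to 11.5). The median of 169908 pairs of domains on different arms was 0.937. Ratios between arms were not rerun with a plain mean.

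**Figure D5:**
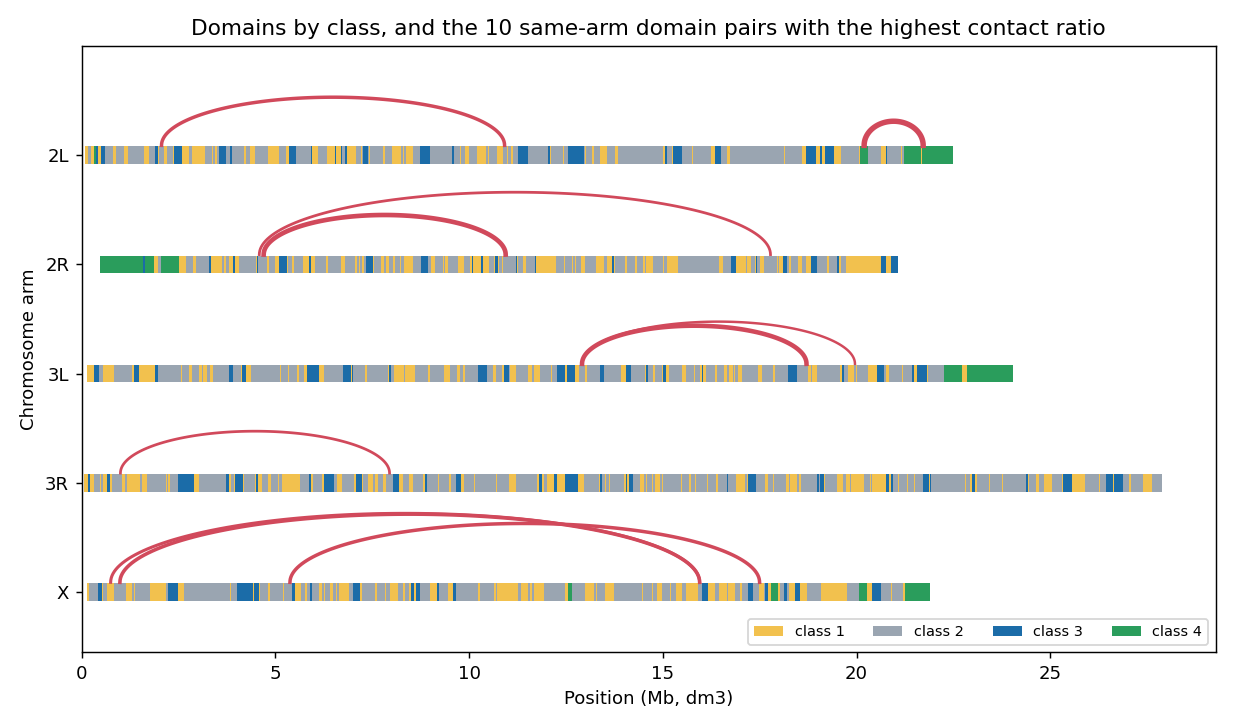
Domains of the 5 large arms (vertical axis) along their positions in Mb (horizontal axis), coloured by class, with arcs joining the 10 same-arm domain pairs of the highest ratio. Arc width grows with the ratio, from 6.14-fold to 19.5-fold; arc height has no scale.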

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

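The alternatives on domain classes, X against autosomal arms, arms as units, the centred matrix, the plain mean between arms, the product of bin totals, loci shifted together, class 3 locus domains alone and the named domain pairs were chosen after seeing the data; the others were fixed before the data were examined. Of 234 values of the comparisons recomputed under an alternative, 193 kept their direction and their side of the threshold. Values without a test were counted as kept if they stayed within the interval of the value in the report. The 193 include values that could not or could hardly change, so this count does not measure stability. Among them are the 21 same-arm counts of Polycomb pairs past the threshold, all 0. Differences between arms (0.41) and of X (-0.22) at other bin sizes are also included, since arm totals do not depend on bin size. Enrichment within domains (log2 0.35 to 0.70), insulation at borders (-0.63 to -0.46), contacts of arm ends, and contacts of class 1 with class 1 (0.39 to 0.99 on the same arm, 0.069 to 0.86 between arms) kept their direction and side of the threshold under all settings run. For arm ends these settings changed only block width, bin size and the test, not the expected contacts. The median slope of contact decay moved to -0.87 over 50 kb to 5 Mb, and the median domain to 67 kb for domains of at least 20 kb, by the filter's construction. The compartment ratio moved to 0.36 at 160 kb, 0.37 beyond 5 Mb and 0.38 after centring. With arms as units the difference between pairs of one chromosome and others was unchanged at 0.41. Its exact permutation p was 0.0667, the smallest that test can give, so it could not pass. That of X (-0.22, exact permutation p = 0.2) did not pass, and could not have done so either. The product of arm totals set the X difference to 0.0022 (exact permutation p = 0.943), since it takes up each arm's total. For class 3 with class 3 on the same arm the value rose past the threshold with the plain mean (0.31), the product of bin totals (0.14) and without 2L (0.090) or 3L (0.11). Between arms it turned to 0.17 and 0.072 with those expected contacts and no longer passed at 80 kb (-0.079) or without 2L (-0.076), 3L (-0.053), 3R (-0.078) or X (-0.074). Class 4 with class 4 turned to -0.49 on the same arm and -0.13 between arms with the plain mean, and on the same arm no longer passed without the outer 10% of the arms (0.042) or without 2L (0.22). Class 2 with class 2 between arms turned to 0.036 with the product of bin totals. Class 2 minus class 4 within domains passed at 5 kb (-0.12) and 20 kb (-0.14). The same-arm median of the Polycomb pairs turned above expectation with the plain mean (0.54) and the product of bin totals (0.16), with either null, and lay on the other side of its draws without the odd skipped cluster (-0.085, permutation p = 0.965). The median between arms rose past the threshold with the plain mean (0.37) and bin totals (0.16) and, against independent draws only, without both Hox complexes (0.042), ANT-C (0.016), BX-C (0.016), salm-salr (0.0050), esg (0.0054) or sna (0.011). The number of Polycomb pairs past the threshold was 0 in all 22 alternatives between arms; on the same arm the count says nothing about stability, since a lone pair could hardly pass. Except where a construction is named, the cause was not tested. Of the values for single named borders and domain pairs, 37 moved beyond their counting interval and 0 changed direction; the 5 borders ranged from -2.002 to -0.70 and the 10 domain pairs from 4.92-fold to 17.4-fold. The log2 ratio of ANT-C with BX-C ranged from 0.43 to 0.94 and that of BX-C with tin-bap-lb from 0.82 to 1.04, in part outside their counting intervals. Not run were the 5 kb table for contact decay, which stops at 0.4 Mb, the stricter part of the borders, as the list has no score for them, and each replicate left out. Other expected contacts were also not run for the within-domain class differences, arm ends, chromosome 4 and the between-arm domain pairs. Nor were they run for the compartment pattern or for the contact density of named domains and of domains with a Polycomb locus. The class difference at borders was computed with a plain mean, and class 2 with class 3 with both other expected contacts. Those values were not kept. No paired analysis was possible because the series has 1 group and its tables name no library. Some single pairs of loci between arms held few contacts, such as Dll with ph at 38 (2.42-fold, 95% Poisson interval 1.71 to 3.32). Whether depth limits these pairs was not tested.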

Other observations

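The tests of rearrangement, of a single junction, of shared reads, of X copy number and of the closer match in element count, and the count of neighbouring classes, were chosen only after the results they bear on were seen; the other tests of the bias model and of class 4 domains were written before their values were known. Domain classes did not follow each other at random along the large arms. Class 4 domains adjoined each other at 20 borders where class orders shuffled within each arm gave 1.05 (SD 1.00; permutation p = 0.0002, the smallest these shuffles can give, adjusted p = 0.000667 over 10 kinds of border). Class 1 met class 2 at 534 borders against 475 (SD 15.4; permutation p = 0.0004, adjusted p = 0.001) and class 1 at 263 against 289 (SD 8.89; permutation p = 0.0046, adjusted p = 0.0092). Class 3 adjoined class 3 at 19 borders against 14.7 (SD 3.46; permutation p = 0.269).

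The 50 same-arm domain pairs with the highest ratio held 19 of class 2 with class 2, where their share of all pairs would give 13.5, 9 of class 1 with class 1 (4.76), 4 of class 2 with class 4 (1.73) and 4 of class 4 with class 4 (0.023). Of the 50 highest between arms, 19 joined class 4 with class 4, where the share would give 0.056, and 3 joined class 2 with class 2 (13.6). These are counts without a test, since pairs share domains. They rest on the authors' expected contacts and were not rerun with a plain mean. With it, class 4 with class 4 between arms stood at -0.13 on the log2 scale over all bins.

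The focal contacts between the 10 named domain pairs may come from chromosome rearrangements in this stock relative to the assembly. A single junction at the pair of 16 kb bins with most contacts is argued against as a common cause of the 10 pairs. It leaves the 2 flanking corners beside the richest corner near background. These stood at 1.99-fold (median of 10 pairs, range 1.37 to 2.98) or 2.20-fold with a plain mean. The median covers the pairs as a set, and some of them share a domain. For a single pair, such as 4,553,850 to 4,610,849 with 17,608,850 to 17,948,849 on 2R (1.37-fold), a junction stays open. Reads shared between similar sequences of a single pair of bins are argued against too, since without all bin pairs that share a bin with the peak the median ratio was 7.48 (range 4.61 to 17.5). Other rearrangements stay open: the excess in the richest of 4 corners was 1.197 times that predicted from the decay of contacts (range 0.456 to 2.01), a value selected upward by that choice, so it decides nothing. The design gives no second group, and no biological explanation was tested.

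Contacts of X with the autosomal arms stood at 0.780 of the autosomal value, and a candidate explanation is that male embryos carry a single X; the labels do not give the embryos' sex. Contacts within X at 50 kb to 2 Mb were 0.666 of the mean of the autosomal arms, between the bounds set for a mixture of both sexes and against it, so copy number cannot be told apart from other causes by this value. The authors' bias model is argued against as the cause: with equal expected contacts for every pair of bins the X value was 0.773 (range 0.724 to 0.836 over 4 arms).

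Of the class 4 domains on the large arms, 7 lay outside the 10% nearest the centromere, and their contacts with centromere-proximal class 4 bins of other arms ranged from 1.097-fold to 2.06-fold. Among windows within 2 Mb that lay outside that part of the arm and held no class 4 bin, their median percentile was 82.8 (range 20.2 to 100), between the bounds set in advance, so that position along the arm stays open. Low numbers of mappable elements stay open too: the median percentile was 72.6 (range 50.2 to 100) among up to 500 windows, a match that took in nearly all windows of the arm and so decides nothing, and 92 (range 60 to 100) among the 50 closest in element count, a spread that reaches well below the bound of 90. The domains 20,099,550 to 20,292,949 on 2L (1.88-fold) and 2,038,650 to 2,500,749 on 2R (2.06-fold) exceeded every window of these sets, but with 440 and 1142 elements they lay below the fewest among their matched windows (445 and 1415). They also lay at 12.2% and 10.7% of the arm from the centromere, so few windows outside the nearest 10% could lie closer to it. Mean log2 contact with block 1 of other arms, the centromere-proximal 10%, fell from 0.40 in block 2 to 0.21 in block 3 and 0.12 in block 4. Position could therefore place these domains above the windows, and their rank decides nothing. No biological explanation was tested.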
